A study of Mus musculus with 4 samples.

How the data were processed

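Expression was read in 4 sorted CD4+ T cell populations, CD25hi Foxp3+, CD25lo Foxp3+, CD25+ Foxp3- and CD25- Foxp3-, each on 1 Affymetrix Mouse Genome 430 2.0 array. Per the labels, spleen and lymph node cells of 25 male Foxp3-GFP knock-in mice (B6/129 F2, aged 5 to 8 weeks) were depleted of cells positive for CD8, B220, CD11b, NK1.1 or DX5 and then sorted on CD4, GFP and CD25. Also per the labels, total RNA was carried through 2 cycles of in vitro amplification before hybridisation. The groups were taken from the sample titles, and each group held 1 array.

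The deposited values are 1 intensity per probe set on a linear scale, positive and not whole numbers, as read from the values themselves. How the authors summarised probes, corrected background and normalized the arrays is not given in the sources used here. The 4 columns had medians between 15.03 and 15.6 and nearly equal quantiles, so they were kept on the deposited scale and converted to log2 without further scaling. This followed a rule fixed beforehand, that columns with medians within 10% are kept.

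Probe sets were joined to genes with the platform's annotation. Of the probe sets, 64 controls were left out, 34958 had exactly 1 gene, 932 had several genes and 9211 were not listed with a gene. Of those with 1 gene, 34754 were matched by Entrez identifier to the mouse RefSeq gene table of assembly GRCm38.p6, which changed no symbol. That table was used for names and for the order of genes beside Foxp3 only, and no coordinates are given. The probe sets covered 18194 genes.

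Values under the 40th percentile of all values, an intensity of 10.1, were set to it. A probe set was kept if its highest value reached the 60th percentile, an intensity of 32.5. A gene with several such probe sets was read from the one with the highest mean log2 intensity. This left 9623 measured genes, 4426 of them with at least 2 probe sets. A fold against an array at the floor is a lower bound and is written as at least. Folds against readings little above the floor, such as those of Kit, Kcnk1, Lrrc75b and Cyp4f18, are uncertain in size and rank.

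Each group has 1 array, so size rules were used and no test was made. A fit by Foxp3 state alone, or by Foxp3 and CD25 without their interaction, was left out, since it would take differences between the sorted populations as its error. The 4 arrays can be paired 2 against 2 in 3 ways, by Foxp3, by CD25 and by neither. A gene counted in a pairing when the lower of one pair exceeded the higher of the other by at least 1.5-fold. In each of the 6 comparisons of 2 arrays a gene counted at 2-fold or more. The pairing by neither marker served as a yardstick of spread between arrays, together with any effect that differs between the marker states.

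The 23 gene lists were written before the data were examined, as were the main settings, the size rules, the alternatives and the rule for naming genes. The lists were Treg, naive T cell, activated and memory T cell, costimulation and TNF receptor, cytokine, chemokine receptor and adhesion, cell cycle, early T cell receptor response, STAT5 target and IL-2 receptor, T follicular helper, helper lineage transcription factor, interferon response, apoptosis, T cell identity, housekeeping, heat shock and stress, cholesterol synthesis and glycolysis genes. A further 5 held markers of B cells, of CD8 T and NK cells, of myeloid and dendritic cells, of red cells and platelets, and of gamma delta T and NKT cells. For each list the median log2 difference of its measured members was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. Foxp3 and Il2ra were left out of list medians. A pair of further marker lists, of innate lymphoid cells and of mast cells and basophils, was written after the data were seen and is used only in the closing section. The lists share genes, and 11 of the 29 measured Treg genes stand on another list.

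By the naming rule, the text names Foxp3 and Il2ra, the 15 genes with the widest gap in each direction for the Foxp3 pairing, 10 for the CD25 pairing and 5 for the third. It also names the 10 highest and 10 lowest genes of CD25hi Foxp3+ and of CD25+ Foxp3- against CD25- Foxp3- cells and of CD25hi against CD25lo Foxp3+ cells, and up to 4 members of each list in the comparison it is described for. Genes known only by clone or locus symbols, 323 of those measured, were counted and not named. Genes named outside this rule in the report, among them list members given with a count of 5 or fewer and the values of Il2, Il21, Fcer1g and H2-Ab1, were chosen after their values were seen.

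Correlations of differences across genes are given with an interval from 500 bootstrap draws over genes. The spread of 1 array was bounded from the double difference of the 4 arrays and from probe sets of the same gene. The counting rules were tested on simulated data with known differences. In the Foxp3 pairing, 44% of simulated 2-fold and 99% of 4-fold differences passed at the upper spread, and 69% and 100.0% at the spread between probe sets.

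The alternatives were quantile normalization, centring on the median of bright probe sets, cyclic loess, no floor, a floor at the 60th percentile, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, and a gap of 2-fold. For list medians all members with a probe set were also used, and for correlations only genes above the 75th percentile in all 4 arrays. Counts without the listed markers of other cell types were added after seeing the data. Probe sets without exactly 1 gene were left out of every count, and those with no listed gene appear only in the closing section. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for quantile and cyclic loess scaling.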

Results

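Gene expression was measured in 4 populations of CD4+ T cells from mice in which green fluorescent protein (GFP) was knocked into the gene for Foxp3, the transcription factor of regulatory T (Treg) cells. Spleen and lymph node cells of 25 male mice were pooled and sorted by GFP, as the mark of Foxp3, and by CD25, the alpha chain of the IL-2 receptor. The 4 populations were CD25hi Foxp3+, CD25lo Foxp3+, CD25+ Foxp3- and CD25- Foxp3- cells. Each was read on 1 whole-genome array, so no group had replicates. The differences below were therefore judged by their size and carry no test. The arrays shared a scale, with median intensities of 15.03, 15.2, 15.4 and 15.6 in the order given above and the highest intensity between 33664 and 40178. Between 39.7% and 40.3% of probe sets in each array reached the filter intensity of 32.5. The number of arrays limits the precision.

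The sort genes followed the labels for Foxp3, and for CD25 in part. Foxp3 read 1308 in CD25hi Foxp3+ cells and 1117 in CD25lo Foxp3+ cells, against 16.8 in CD25+ Foxp3- and 17.6 in CD25- Foxp3- cells, both under the filter intensity. Il2ra, which encodes CD25, read 1562 in CD25hi Foxp3+ cells and 22.3 in CD25- Foxp3- cells, a 70.0-fold difference. Its intensity was nearly the same in CD25lo Foxp3+ cells, at 288, and in CD25+ Foxp3- cells, at 283. A second Il2ra probe set gave 417, 84.2, 114 and 9.57 in the order of the populations above, which follows the CD25 labels. Since the sort was made on them, neither gene is counted in a list median.

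By correlation and by the number of 2-fold differences, whole profiles were closest between the Foxp3+ pair. Across 9623 measured genes the log2 intensities of CD25hi and CD25lo Foxp3+ cells had a Pearson r of 0.972, and 550 genes lay at least 2-fold apart. By the median absolute log2 difference, CD25hi Foxp3+ cells lay almost as close to CD25- Foxp3- cells, at 0.279, as to CD25lo Foxp3+ cells, at 0.273. The pair farthest apart was CD25+ Foxp3- and CD25- Foxp3- cells, with an r of 0.921 and 1780 genes at least 2-fold apart. These correlations are across genes, which are not independent replicates.

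The first comparison asks which genes go with Foxp3 in both Foxp3+ against both Foxp3- populations. Both Foxp3+ arrays were far above both Foxp3- arrays for Klrg1, an inhibitory receptor of effector lymphocytes, and for Itgae, the CD103 integrin chain that binds E-cadherin. Klrg1 read 1085 and 2429 in the Foxp3+ arrays against 79.1 and 68.4 in the Foxp3- arrays. Itgae read 4994 and 4421 against 377 and 296. Both were far below the Foxp3- arrays for Pde3b, a phosphodiesterase that breaks down cyclic AMP, which read 213 and 281 against 2742 in CD25+ Foxp3- and 6467 in CD25- Foxp3- cells. The cytokine gene Il4 read 11.2 and 10.8 in the Foxp3+ arrays, close to background, against 145 and 72.0.

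By the rule that the lower of one pair must exceed the higher of the other by at least 1.5-fold, 269 genes were higher and 186 lower in both Foxp3+ arrays, together 4.73% of measured genes. At a gap of 4-fold the counts were 18 and 19. Apart from Foxp3, the widest gaps upward were in Klrg1 with 13.7-fold, Neb (nebulin, a muscle filament protein) with 13.1-fold, Itgae with 11.7-fold and Prg4 (lubricin) with 9.22-fold. They were followed by Ncmap with 6.17-fold, the laminin chain Lamc1 with 5.65-fold, Entpd1 with 5.39-fold, Csrp2 with 5.37-fold and the adhesion molecule Epcam with 5.15-fold. Neb, Ncmap, Lamc1 and Csrp2 read between 10.1 and 21.0 in the Foxp3- arrays, at or near the floor, so the size and rank of their gaps are uncertain. Itih5, Rapgef5, Il10, the kinase Matk and the clotting factor chain F13a1 had gaps between 4.31-fold and 4.83-fold. Entpd1 encodes CD39, which breaks down extracellular ATP, and Il10 encodes a cytokine that restrains immune responses. Il10 read 207 and 395 against 44.1 in CD25+ Foxp3- cells and background in CD25- Foxp3- cells.

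Downward, the gap was 9.75-fold for Pde3b and 9.46-fold for St6galnac2, a sialyltransferase. It was 6.67-fold for Crtam (an adhesion molecule of cytotoxic lymphocytes), 6.59-fold for Epas1 (the oxygen-regulated factor HIF-2 alpha), 6.57-fold for Mctp2 and 6.43-fold for Il4. The last pair read between 10.8 and 18.3 in the Foxp3+ arrays, near the floor of 10.1, so the size and rank of their gaps are uncertain. Fasl, the death ligand, had a gap of 5.95-fold and read 53.8 and 77.5 against 514 and 461. St3gal6, another sialyltransferase, followed with 5.43-fold and Tgfbr3, the betaglycan receptor for TGF-beta, with 5.37-fold. Lypd6b, Mzb1, App, Igkv15-103, Atp8b4 and Klrd1 had gaps between 4.78-fold and 5.17-fold. Mzb1 and Igkv15-103 are genes of the B cell lineage and Klrd1 encodes CD94, a receptor of NK and CD8 T cells. Igkv15-103 was at the floor in both Foxp3+ arrays, so its gap is a lower bound.

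**Figure D1:**
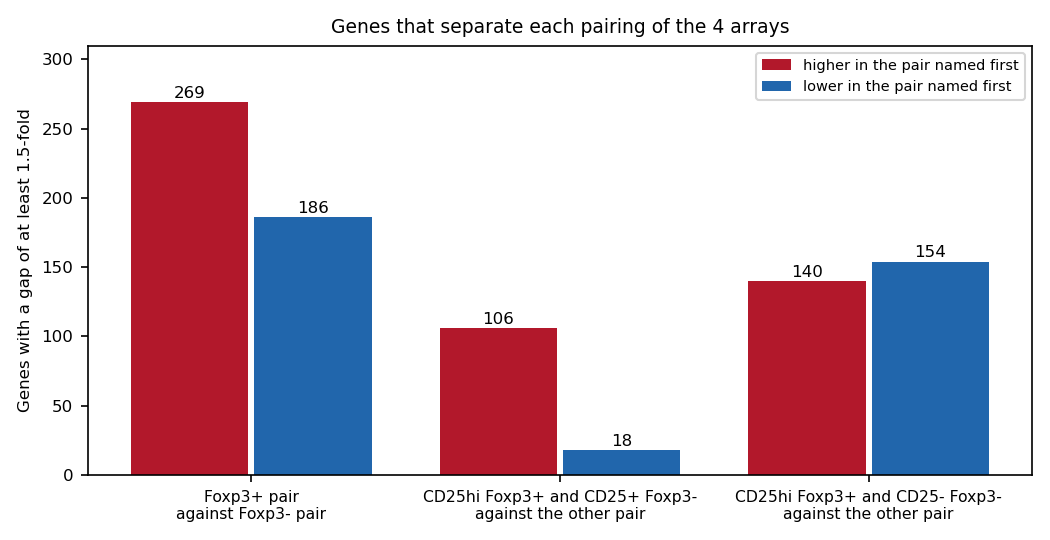
Bars show the number of genes (vertical axis, starting at 0) that separate the 4 arrays into each of the 3 possible pairings with a gap of at least 1.5-fold. The Foxp3 pairing separated 269 and 186 genes, the CD25 pairing 106 and 18, and the pairing that follows neither marker 140 and 154.

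Of the 29 measured genes on the Treg list, Foxp3 and Il2ra apart, 21 were higher in both Foxp3+ arrays, none was lower and 8 did not pass the rule. This list is in part known from profiling of this kind and is not independent evidence. Ctla4, the receptor that takes CD80 and CD86 from antigen-presenting cells, read 10132 and 12173 against 2682 and 852. Ikzf2 (Helios) read 4891 and 7034 against 1917 and 424. Gpr83 read 4426 and 1350 against 315 and 323, and Nrp1 read 3683 and 5447 against 1053 and 281. The 8 genes outside the rule were Ebi3, Ecm1, Icos, Lag3, Penk, Plagl1, Rgs16 and Socs2. Lag3 read 123 and 113 in the Foxp3+ arrays, 157 in CD25+ Foxp3- cells and 27.7 in CD25- Foxp3- cells.

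**Figure D2:**
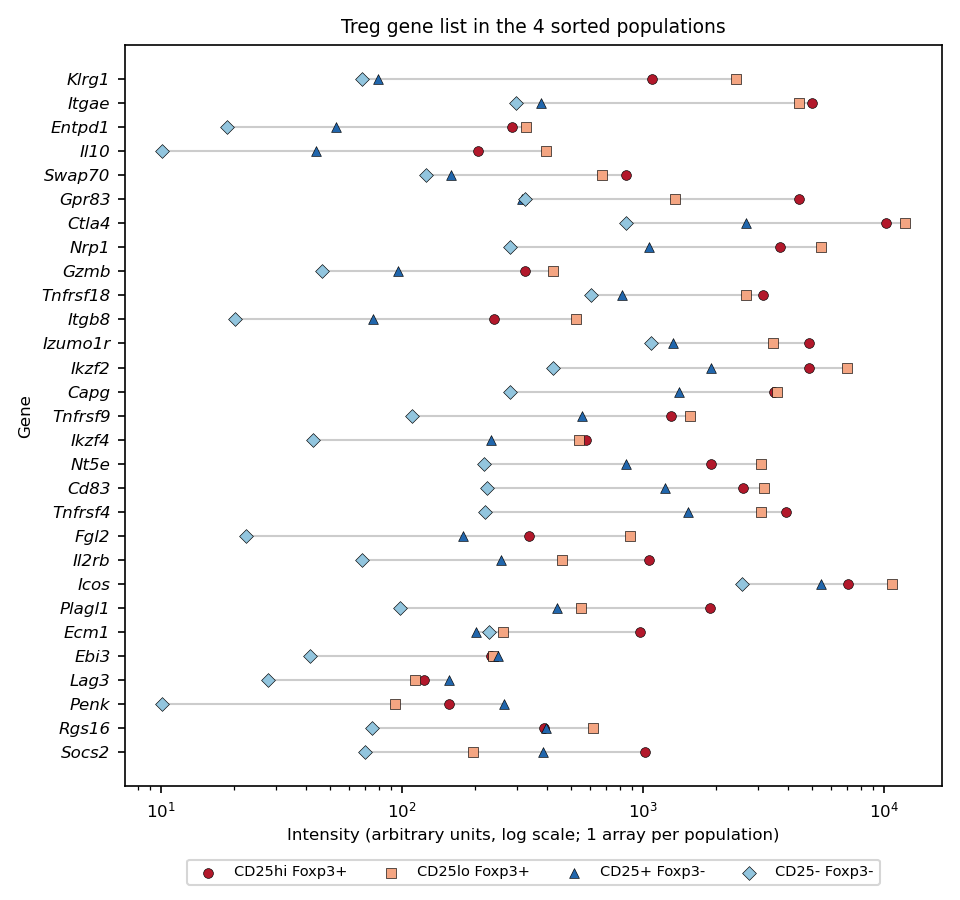
Each line is 1 gene of the Treg list and each symbol its intensity (arbitrary units, log scale) in 1 of the 4 arrays, with genes in falling order of the gap between Foxp3+ and Foxp3- arrays. For 21 of the 29 genes both Foxp3+ arrays stand at least 1.5-fold above both Foxp3- arrays, and CD25+ Foxp3- cells lie at least 2-fold above CD25- Foxp3- cells in 22.

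Among the costimulation and TNF receptor genes 7 of 22 were higher with Foxp3 and 1 was lower, and 9 of the 22 stand on another list as well. Tnfrsf1b, the second TNF receptor, read 2051 and 2289 against 575 and 274, and Tnfrsf18 (GITR) read 3129 and 2672 against 815 and 607. The one lower was Tnfsf14 (LIGHT). Chemokine receptor and adhesion genes had 5 of 25 higher, namely Ccr4, Ccr8, Icam1, Itgae and Itgb8, and 1 lower, Cxcr6. Ccr8 read 185 and 194 against 53.2 and 19.2. Among the lineage transcription factors 3 of 21 were higher, Batf, Ikzf3 and Nfil3, and 1 was lower, Eomes. Members named because their list had 5 or fewer past the rule were chosen after their values were seen.

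Activated and memory genes had 4 of 24 higher, Anxa2, Lgals1, Prdm1 and S100a6, and 2 lower, Id2 and Nkg7. Prdm1 (Blimp-1) read 280 and 627 against 74.7 and 41.2. Naive T cell genes had 3 of 17 lower and none higher. These were Dapl1, Igfbp4 and Pde3b. Of 19 cytokine genes, Il10 was higher and Il4 and Il21 were lower. The T follicular helper list had 3 of 15 lower, Il4, Il21 and Sostdc1, and none higher, and 10 of the 15 are held by another list. In the STAT5 and IL-2 receptor list Il2rb and Jak3 were higher and Pim2 was lower out of 18.

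Other lists had few genes past the rule, although the medians of some were above most random lists. The median log2 difference between the means of the Foxp3+ and Foxp3- arrays was 0.647 for cell cycle genes and 0.351 for early T cell receptor response genes, both above all random lists. It was 0.359 for apoptosis genes (percentile 99.96), 0.229 for T cell identity genes (99.47), 0.086 for interferon response genes (87.7), 0.004 for glycolysis and for housekeeping genes and -0.154 for cholesterol synthesis genes. Against CD25+ Foxp3- cells alone, the cell cycle medians of CD25hi and CD25lo Foxp3+ cells were -0.48 and -0.23. The positive cell cycle value thus comes from the low CD25- Foxp3- array. Against CD25- Foxp3- cells alone, the T cell identity medians were -0.145 and 0.003, so that value comes from the low CD25+ Foxp3- array. Of 24 early T cell receptor response genes only Dusp4 was higher, at 2090 and 1840 against 830.4 and 120, and none was lower. Of 27 interferon response genes Gbp3 and Isg20 were higher and none was lower. Among 19 apoptosis genes Pmaip1, which encodes Noxa, was higher and Fasl lower. The glucose transporter gene Slc2a3 was higher among 13 glycolysis genes and none was lower. No gene passed the rule in either direction among 39 cell cycle genes, 18 T cell identity genes, 15 housekeeping genes and 13 cholesterol synthesis genes.

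Some markers of other cell types moved with the same split. Lower in both Foxp3+ arrays were 9 of 14 markers of CD8 T and NK cells, 5 of 11 B cell markers, 2 of 16 myeloid markers, 3 of 4 red cell markers and 1 of 4 markers of gamma delta T and NKT cells. Cd8a read 101 and 83.7 against 185 and 351, and Ms4a1 (CD20) read 15.9 and 24.7 against 66.7 and 145. H2-Aa, an MHC class II gene, read 132 and 375 against 1877 and 1098. The red cell genes were Alas2, Car1 and Klf1, and Car1 read 27.1 and 94.9 against 257 and 416. The B cell genes were Ly86, Ms4a1 and the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1. Cd79b went the other way without passing the rule, at 97.2 and 118 against 58.4 and 69.2. The 2 myeloid genes were Tyrobp and S100a9, and the gene of the last list was Zbtb16. Higher were Gzmb, which the Treg list also holds, and Fcmr. Of the 14 CD8 T and NK markers 10 reached the filter in all 4 arrays, as did 7 of the 11 B cell markers, 7 of the 16 myeloid markers, 1 of the 4 red cell markers and 1 of the 4 markers of gamma delta T and NKT cells. The others passed it through the arrays where they are high, which helped to decide what was measured. Of 14 heat shock and stress genes 1 passed the rule, Hspa1a, which was lower with 173 and 433 against 738 and 1039.

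Without any listed marker of another cell type, 267 genes were higher and 166 lower with Foxp3. As a yardstick, the pairing that follows neither marker separated 294 genes. With no difference at all, each pairing would separate 33.3% of genes by some gap, and the Foxp3 pairing did so for 31.9%, the CD25 pairing for 27.2% and the third for 40.6%.

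The next comparison sets cells with both markers against cells with neither. CD25hi Foxp3+ cells had 682 genes at least 2-fold higher and 360 at least 2-fold lower than CD25- Foxp3- cells. Foxp3 was 74.4-fold and Il2ra 70.0-fold higher. Cyp4f18, a fatty acid hydroxylase, came next at 64.9-fold, with 980 in CD25hi Foxp3+ cells and no more than 49.9 in any other array. Gsta4, a glutathione transferase, was 31.0-fold higher and the syndecan gene Sdc4 at least 28.8-fold. Il10 was at least 20.5-fold higher, the protease gene Capn3 19.8-fold and the decoy IL-1 receptor Il1r2 19.5-fold. Plagl1, a zinc finger factor, was 19.2-fold and the netrin Ntn4 19.0-fold higher.

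Lowest against CD25- Foxp3- cells was Pdlim4, at least 45.0-fold lower, since it was at the floor in both Foxp3+ arrays. App, the amyloid precursor, was 31.3-fold lower, Pde3b 30.4-fold and Mctp2 26.9-fold. App and Mctp2 read 16.9 and 11.8 in CD25hi Foxp3+ cells, near the floor, so the size and rank of their folds are uncertain. Lrrc75b was 25.9-fold, Atp8b4 25.7-fold and Dapl1 24.0-fold lower. Vipr1, a receptor for vasoactive intestinal peptide, was 20.9-fold, the transporter gene Slc16a5 20.4-fold and Lypd6b 17.3-fold lower. CD25+ Foxp3- cells lay between the extremes for Dapl1, at 639 against 163 in CD25hi Foxp3+ and 3909 in CD25- Foxp3- cells.

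All 29 Treg genes were at least 2-fold higher in CD25hi Foxp3+ than in CD25- Foxp3- cells, with a median log2 difference of 3.57, above all 10000 random lists matched on expression. Such a percentile describes these arrays only. Cell cycle genes followed with a median of 1.30, with 28 of 39 at least 2-fold higher and none lower. Costimulation genes had a median of 0.84 and chemokine receptor and adhesion genes one of 0.55. Activated and memory genes had a median of 0.645, with 8 of 24 at least 2-fold higher and 4 lower, and T follicular helper genes one of -0.433. The naive list had a median of -0.67, with 5 of 17 at least 2-fold lower, Actn1, Dapl1, Igfbp4, Lef1 and Pde3b, and 1 higher, Ccr9. The medians of the marker lists were -1.17 for B cells, -1.45 for CD8 T and NK cells, -1.68 for myeloid cells and -2.73 for red cells.

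CD25lo Foxp3+ cells had 875 genes at least 2-fold higher and 662 lower than CD25- Foxp3- cells. Their Treg median was close to that of CD25hi Foxp3+ cells, at 3.67, and 28 of 29 at least 2-fold higher. Activated and memory genes were further apart than in CD25hi Foxp3+ cells, with a median of 1.53 and 14 of 24 at least 2-fold higher. S100a4, a calcium-binding protein of effector and memory T cells, read 9154 against 572. The naive median was -1.43, with 11 of 17 at least 2-fold lower. The medians were 1.66 for cell cycle, 1.47 for chemokine receptor and adhesion genes and 0.66 for the lineage transcription factors. They were -1.70 for CD8 T and NK markers, -0.52 for B cell, -0.47 for myeloid and -2.29 for red cell markers.

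**Figure D3:**
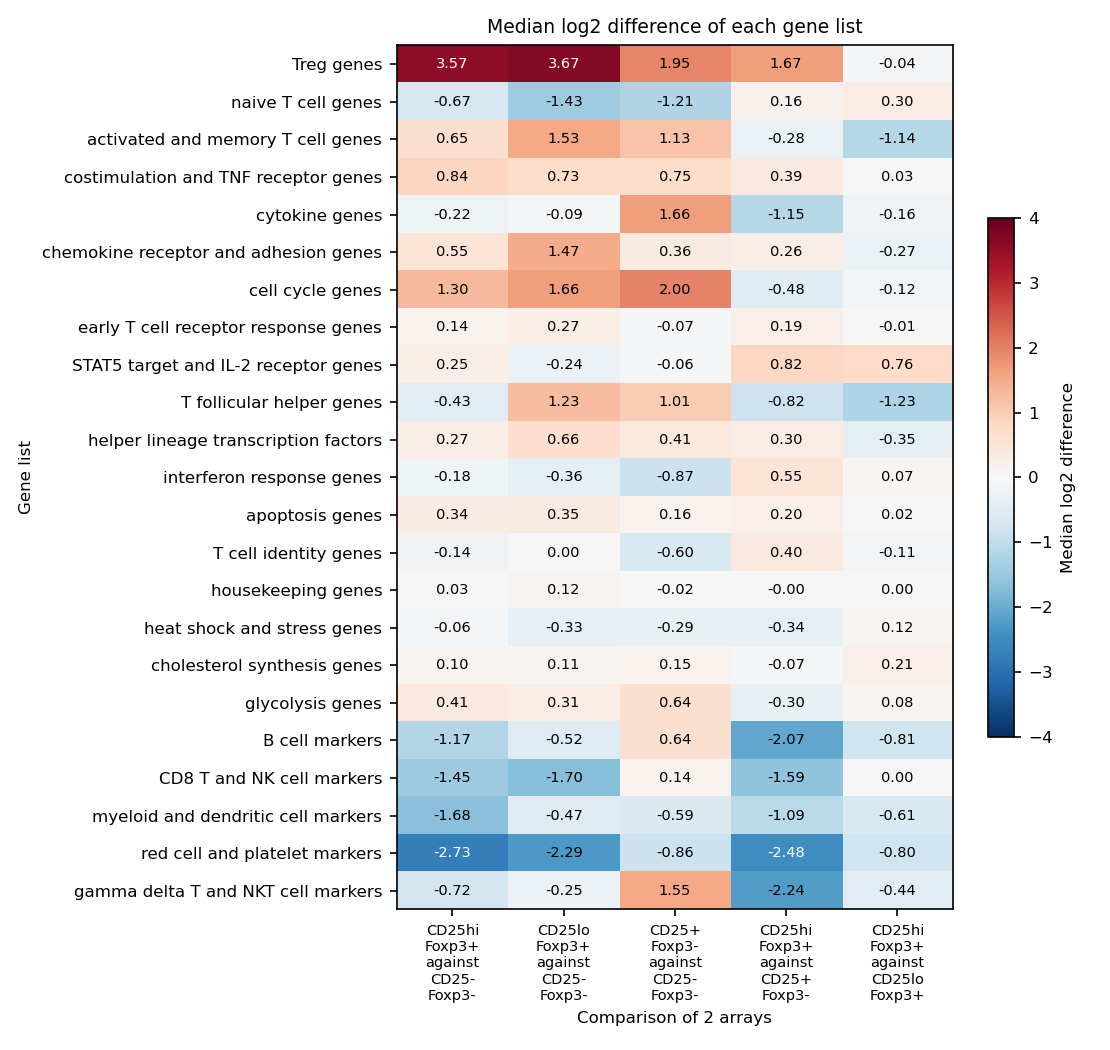
Each cell gives the median log2 difference in intensity of 1 gene list (vertical axis) in 1 comparison of 2 arrays (horizontal axis), in red where the array named first is higher and in blue where it is lower. The Treg list has medians of 3.57, 3.67 and 1.95 against CD25- Foxp3- cells, and the cell cycle list 1.30, 1.66 and 2.00.

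CD25+ Foxp3- cells, which bear CD25 without Foxp3, showed the widest differences from CD25- Foxp3- cells, with 1161 genes at least 2-fold higher and 619 lower. They alone read high for Il2, the T cell growth factor, at 286 against 17.3, and for Il21, a cytokine that helps B cells, at 1794 against 122. Cntn1, a neural adhesion molecule, was at least 57.7-fold higher, with 583 in these cells and floor values in the other 3 arrays. The receptor kinase gene Kit read 399 and was 34.1-fold higher. Igfbp4, which binds insulin-like growth factors, was 6.62-fold lower, at 1996 against 13217.

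The other genes highest in CD25+ over CD25- Foxp3- cells were Klrb1f, a lectin-like receptor, at least 36.6-fold, the potassium channel Kcnk1 with 32.1-fold, and Penk (proenkephalin) and Pxdc1, at least 26.0-fold and 25.0-fold. They were followed by Hmgn3 with 24.7-fold, the Notch ligand Dll1 with at least 24.7-fold, Dtl with 21.4-fold and Sdc4 with at least 21.1-fold. Dtl is a part of a ubiquitin ligase active in DNA replication and read 613 against 28.6. Lowest were Lrrc75b with 14.9-fold, Pdlim4 with 13.5-fold, Ampd1 (AMP deaminase) with 9.18-fold, Arhgap29 with 7.85-fold and Tdrp with 7.24-fold. The interferon-induced gene Oas2 was 7.10-fold lower, Cnga1 6.89-fold, Dapl1 6.12-fold and Vipr1 6.001-fold.

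Of 19 measured cytokine genes 12 were at least 2-fold higher in CD25+ than in CD25- Foxp3- cells and none was lower, with a median log2 difference of 1.66. Only 8 of the 19 reach the filter in all 4 arrays, and Ccl1, Il2, Il13, Il17a and Xcl1 pass it through the CD25+ Foxp3- array alone, so the difference itself helped to decide which genes were measured. Over all 27 cytokine genes with a probe set the median was 0.861. Il2 was 16.5-fold, Il21 14.7-fold and Ccl1 12.2-fold higher, and Ifng read 1146 against 288. Cell cycle genes had a median of 2.00, the highest of the 3 comparisons with CD25- Foxp3- cells, and 34 of 39 were at least 2-fold higher. Mcm5, a part of the replicative helicase, read 7619 against 1514, and Cdc6, which loads it, read 756 against 70.8. Even without Foxp3, 22 of 29 Treg genes were at least 2-fold higher, with a median of 1.95. Activated and memory genes had a median of 1.13, T follicular helper genes 1.01, costimulation genes 0.75 and glycolysis genes 0.64. Interferon response genes had a median of -0.87 with 11 of 27 at least 2-fold lower and 2 higher, and the naive list had a median of -1.21.

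Markers of gamma delta T and NKT cells had a median of 1.55 over only 4 genes, 3 of them at least 2-fold higher. These were Blk, Cd160 and Zbtb16. B cell markers had a median of 0.64, CD8 T and NK markers 0.14, myeloid markers -0.59 and red cell markers -0.86. With the filter at the 75th percentile, which leaves fewer of them, the red cell median was 0.80. Fcer1g, a signalling chain of Fc receptors from the myeloid list, read 294 against 21.5. The T cell identity list had a median of -0.60, though Cd4 read 2434 and 2948. The ratio of 3' to 5' signal for Actb, a sign of RNA integrity and amplification, was 1.94 in CD25hi Foxp3+, 2.21 in CD25lo Foxp3+, 2.65 in CD25+ Foxp3- and 2.29 in CD25- Foxp3- cells. For Gapdh it was 2.404, 2.33, 2.28 and 3.21 in the same order.

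**Figure D4:**
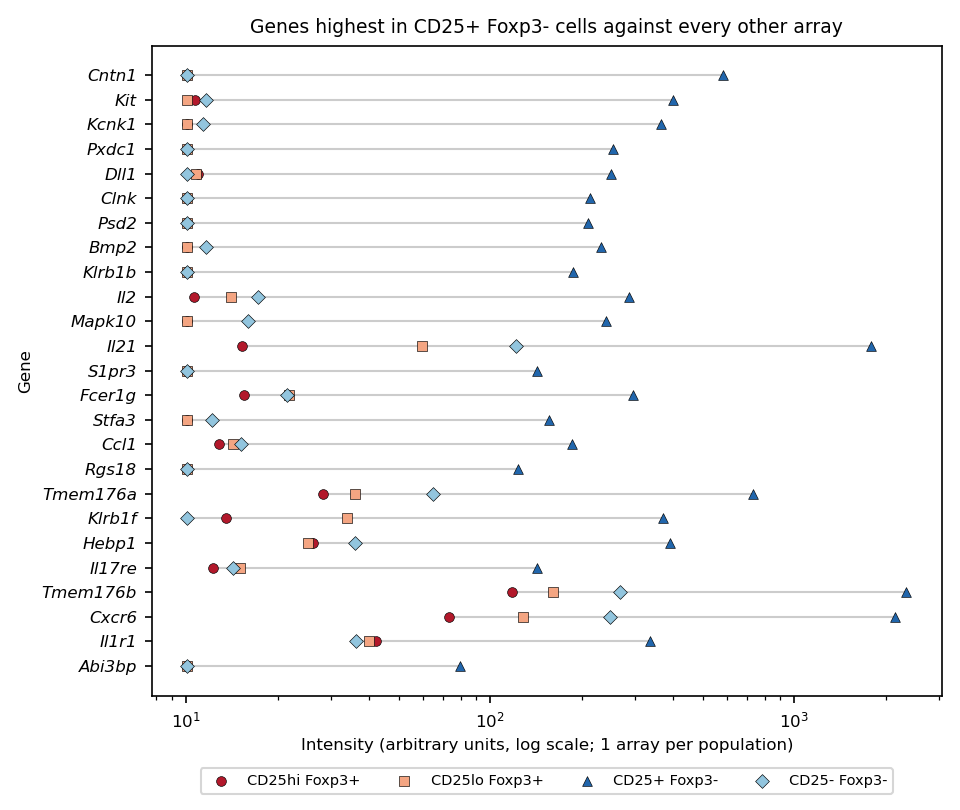
Each line is 1 gene and each symbol its intensity (arbitrary units, log scale) in 1 of the 4 arrays, for the 25 named genes that stood highest in CD25+ Foxp3- cells above every other array. Cntn1 reads 583 and Il21 1794 in CD25+ Foxp3- cells, and many of the other values lie at the floor of 10.1.

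Setting CD25hi Foxp3+ against CD25+ Foxp3- cells compares cells that bear CD25 with and without Foxp3, although Il2ra was 5.53-fold higher in the former. There 464 genes were at least 2-fold higher and 658 lower. Treg genes had a median of 1.67, with 23 of 29 at least 2-fold higher, among them Gpr83 with 14.0-fold and Itgae with 13.2-fold. Cytokine genes had a median of -1.15, with 10 of 19 at least 2-fold lower and Il10 higher. T follicular helper genes had a median of -0.82 and cell cycle genes -0.48, whereas STAT5 and IL-2 receptor genes had 0.82 and interferon response genes 0.55. B cell markers had a median of -2.07, CD8 T and NK markers -1.59, myeloid markers -1.09, red cell markers -2.48 and gamma delta T and NKT markers -2.24. CD25lo Foxp3+ against CD25+ Foxp3- cells gave 497 genes higher and 870 lower, with a Treg median of 1.49.

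Among Foxp3+ cells, the level of CD25 is compared within 1 Foxp3 state. CD25hi cells had 309 genes at least 2-fold higher and 241 lower than CD25lo cells. Cyp4f18 was 19.6-fold higher, the cilia gene Drc1 12.4-fold and Gata1, a factor best known from red cell development, 10.2-fold. Drc1 read 11.8 in CD25lo cells, near the floor, so the size and rank of its fold are uncertain. Prkar1b was at least 9.21-fold, Ntn4 8.49-fold and Treml2 7.58-fold higher. Ampd1 was 6.11-fold, the lysine methyltransferase gene Smyd2 6.06-fold, Il2ra 5.42-fold and Arhgap20 5.28-fold higher. The CD25lo cells were higher by 14.8-fold for Psg28, 7.06-fold for Tktl1 and at least 6.23-fold for Cd244a. Gzmk (granzyme K) was at least 5.99-fold and the adhesion molecule gene Vcam1 5.00-fold higher in them. Myo1f was 4.81-fold, Pak3 at least 4.71-fold and Sccpdh 4.60-fold higher, and Tox2 was 4.39-fold and Nectin3 at least 4.18-fold higher.

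Treg genes went both ways between the Foxp3+ arrays, with 5 of 29 at least 2-fold higher in CD25hi cells and 3 in CD25lo cells and a median of -0.04. The 5 were Ecm1, Gpr83, Il2rb, Plagl1 and Socs2, and the 3 were Fgl2, Itgb8 and Klrg1. Genes of the IL-2 receptor, its signal chain and STAT5 targets had a median of 0.76, with 7 of 18 at least 2-fold higher and 1 lower. Socs2 read 1017 against 197, Bcl2 2653 against 732 and Cish 1656 against 609.8. The lower one was Bcl6, at 183 against 465. Activated and memory genes had a median of -1.14, with 13 of 24 at least 2-fold lower and none higher in CD25hi cells. S100a6 read 1503 against 4516 and Itgb1 read 1793 against 6527. The T follicular helper list had a median of -1.23, with 10 of 15 at least 2-fold lower, such as Maf with 1942 against 6040 and Cxcr5 with 402 against 992. In that list 1 gene was at least 2-fold higher, Tnfsf8, at 187 against 63.3. B cell markers had a median of -0.81, myeloid markers -0.61, red cell markers -0.80 and CD8 T and NK markers 0.00. H2-Ab1 read 48.3 against 129 and Lyz2 read 27.8 against 113.

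Few genes followed the CD25 labels across both Foxp3 states. Il2ra did not pass this rule by either probe set, since CD25lo Foxp3+ and CD25+ Foxp3- cells read 288 and 283 by one and 84.2 and 114 by the other, so the pairing goes by the names of the sorts. CD25hi Foxp3+ and CD25+ Foxp3- cells stood at least 1.5-fold above both other arrays for 106 genes and below them for 18. The gap was 4.05-fold both for Lad1 and for Shmt1, an enzyme of one-carbon metabolism, which read 257 and 665 against 50.8 and 63.6. Lta (lymphotoxin alpha) had a gap of 2.79-fold, Zbed5 2.65-fold, the kinase gene Mapk12 2.51-fold and Smyd2 2.48-fold. Ydjc, the hexokinase gene Hk2, the deaminase gene Dctd and the DNA repair nuclease gene Exo1 had gaps between 2.28-fold and 2.402-fold. Downward gaps were 2.18-fold for Sntb1, 2.01-fold for Hsd11b1, which activates glucocorticoids, 1.73-fold for Il6ra and 1.65-fold for the chemokine gene Ccl5. Depp1, Lyz2, Dennd6b, Klf6, Leprotl1 and Lyz1 had gaps between 1.56-fold and 1.63-fold. The lysozyme genes Lyz1 and Lyz2 are myeloid markers, and 2 of 16 myeloid markers were lower with CD25. Lyz1 was read from a probe set that can match several transcripts and was not measured without such probe sets. The 2 lysozyme readings may therefore not be independent. Of 39 cell cycle genes 3 were higher, Cdc6, Mcm2 and Mcm5, and so was Myc among the early response genes. With a gap of 2-fold the counts for this pairing were 27 and 2.

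The pairing that follows neither marker separated more genes than CD25 did. CD25hi Foxp3+ and CD25- Foxp3- cells were both higher than the other two populations for 140 genes and lower for 154, which became 99 and 196 under cyclic loess scaling. Ampd1 had the widest gap upward with 5.72-fold, and Treml2 followed with 3.65-fold, Cdk12 with 3.15-fold, Sorcs2 with 2.74-fold and Rab3ip with 2.59-fold. CD25lo Foxp3+ and CD25+ Foxp3- cells were together higher for Tbx21 (T-bet, the Th1 factor) with a gap of 3.29-fold, at 67.6 and 227 against 20.5 and 20.2. Asb2 followed with 2.95-fold, the receptor gene Cd244a with 2.92-fold, Eea1 with 2.72-fold and Ccdc28b with 2.65-fold. Lgals3, Maf and Tbx21 of the activated and memory list were in this group, and that list had a median of 1.10 in these 2 arrays over the others. Other lists were high there too, with 1.18 for Treg genes, 0.995 for cell cycle genes, 0.944 for cytokine genes and 0.979 for B cell markers, of which 5 of 11 were at least 2-fold higher. This median also rises for a list that is low in CD25- Foxp3- cells alone. Treg and cell cycle genes had medians of only -0.04 and -0.12 between CD25hi and CD25lo Foxp3+ cells. In this pairing 0 of 29 Treg genes and 2 of 39 cell cycle genes passed the rule.

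Differences with Foxp3 were only loosely alike in the 2 pairs of populations that differ in Foxp3. Neither pair holds CD25 constant, since Il2ra was 5.53-fold higher in CD25hi Foxp3+ than in CD25+ Foxp3- cells and 12.9-fold higher in CD25lo Foxp3+ than in CD25- Foxp3- cells, so both differences carry one in CD25 too. Across 9623 genes, the difference between CD25hi Foxp3+ and CD25+ Foxp3- cells correlated with that between CD25lo Foxp3+ and CD25- Foxp3- cells with a Pearson r of 0.13 (bootstrap interval over genes 0.092 to 0.156) and a Spearman rho of -0.040. Among genes above the 75th percentile in all 4 arrays r was -0.023. At least 2-fold higher in both were 156 genes and lower in both 137, where independent draws would give 42.2 and 45.3. Such draws take all genes as equally variable, so part of the excess may come from genes that vary more. The difference with CD25 in Foxp3+ cells correlated with that in Foxp3- cells with an r of -0.146 and a rho of -0.168.

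Without replicates, the spread could be bounded but not measured. From the double difference of the 4 arrays, an upper estimate of the SD of 1 log2 difference was 0.60, which includes true differences. Probe sets of the same gene gave 0.25 to 0.43, without variation between sorts or mice. Among genes at least 2-fold apart, a second probe set of the gene differed in the same direction in 89.1% to 96.5%. In the pairings a second probe set passed the rule in the same direction for 89 of 165 genes by Foxp3, 13 of 29 by CD25 and 29 of 127 by neither, and in the opposite direction for none. At the upper spread, the genes simulated without a difference gave counts of 141 and 138 in the Foxp3 pairing and 118 and 119 in the CD25 pairing. They gave 141 and 143 in the pairing by neither and 452 to 505 per direction in the comparisons of 2 arrays. The observed counts were lower in the CD25 pairing, at 106 and 18, and between CD25hi and CD25lo Foxp3+ cells, at 309 and 241. The upper spread is thus too wide for these, and their counts show no difference beyond it. In each other comparison of 2 arrays the observed count was above the simulated one in at least 1 direction. With the spread between probe sets no more than 10 genes per direction passed. Each simulation used a single spread for all genes, so its counts are no upper bound for dim genes.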

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

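The tests described in this part were chosen only after the results they bear on were seen, and the differences listed were not themselves tested, since each population has 1 array. Some genes differed in opposite directions in the 2 pairs of populations that differ in Foxp3. Each pair also differs in CD25, with Il2ra 5.53-fold and 12.9-fold higher on the Foxp3+ side, so these are not shown to be effects of Foxp3 that turn with CD25. At least 2-fold higher in CD25hi Foxp3+ than in CD25+ Foxp3- cells and at least 2-fold lower in CD25lo Foxp3+ than in CD25- Foxp3- cells were 39 genes, among them Ampd1, Treml2, Cdk12 and Adcy6, where independent draws would give 31.9. The reverse held for 104 genes, such as Hmgn3, Rbm26, Asb2 and Tnfsf11, where independent draws would give 59.8. These genes were named after their values were seen.

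Among the gene lists, 3 had medians of opposite sign in the same 2 comparisons with each at least 0.32 log2 from 0. The cell cycle median was -0.48 between CD25hi Foxp3+ and CD25+ Foxp3- cells and 1.66 between CD25lo Foxp3+ and CD25- Foxp3- cells. The T follicular helper median was -0.82 and then 1.23, and the interferon response median was 0.55 and then -0.36. Neither of the 2 differences behind each pair of values is replicated, and their difference was not tested.

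Probe sets with no listed gene lie outside every count of the report, and some of them differed between the arrays. Of 2102 that were measured, 46 were at least 1.5-fold higher and 32 lower in both Foxp3+ arrays. The widest gap upward was in a probe set that read 540.0 and 1203 against 83.8 and 59.7, and the widest downward was in one that read 132 and 102 against 1113 and 910.4. Of the same 2102 probe sets, the pairing by neither marker separated 72 higher and 23 lower in CD25hi Foxp3+ and CD25- Foxp3- cells. That pairing is the yardstick of spread between arrays, so the counts by Foxp3 alone do not show a difference beyond that spread.

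The first pattern weighed is that some listed genes of B, CD8 T, NK, myeloid and red cells were higher in both Foxp3- arrays. Among myeloid markers these were 2 of 16, where 186 of all 9623 measured genes were lower with Foxp3. The myeloid median was -0.899 log2 between the means of the Foxp3+ and Foxp3- arrays, below all random lists. Against CD25- Foxp3- cells it was -1.682 in CD25hi and -0.471 in CD25lo Foxp3+ cells. Against CD25+ Foxp3- cells it was -1.093 and 0.034, so that list did not follow the pattern in every comparison. A single B cell source for the B cell and MHC class II genes would move both alike between the Foxp3- arrays. From CD25- to CD25+ Foxp3- cells the median of H2-Aa, H2-Ab1 and H2-Eb1 exceeded that of the 7 other B cell markers by 1.27 log2, with an error of 0.51. Cd74, which works with MHC class II, was left out of both sides and rose most, from 681 to 2806. The 7 went both ways, though, with Cd22 at 81.4 against 31.6 and Blk at 46.3 against 20.03 but Ms4a1 at 66.7 against 145, and only 3 of them reached the filter in all arrays. This leaves B cells as the only source open. Without the listed markers 166 of the 186 genes lower with Foxp3 are left, which decides nothing, since with 48 marker genes measured no fewer than 138 could have been left. Other cells that passed the depletion may thus have added listed and unlisted transcripts, and differences between T cells, untested here, stay open beside them.

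The second pattern is the set of genes that joined CD25lo Foxp3+ with CD25+ Foxp3- cells against the other two populations. The scalings tried do not account for the whole of it, since of the 294 genes on the deposited scale 268, 267 and 253 passed in the same direction under quantile normalization, median centring and cyclic loess. The balance moved, however, with 99 genes higher and 196 lower in CD25hi Foxp3+ and CD25- Foxp3- cells under cyclic loess, against 140 and 154. Noise of single probe sets alone does not account for it either, since of 127 genes with another probe set 29 were separated the same way by it and 0 the opposite way. The activated and memory list had a median of 1.10 in these 2 arrays, at the percentile 100 of random lists, as more activated or memory cells in both sorts would give. Such a median was not particular to that list, since 11 of the 23 lists lay past the upper limit set for random lists. Among them were the Treg list with 1.18, the cell cycle list with 0.995, B cell markers with 0.979 and gamma delta T and NKT markers with 0.997. However, this median also rises for a list that is low in CD25- Foxp3- cells alone. Between CD25hi and CD25lo Foxp3+ cells the Treg and cell cycle medians were -0.04 and -0.12. Those of activated and memory genes and of B cell markers were -1.14 and -0.81. The Treg and cell cycle lists thus do not speak against more activated or memory cells. Of the 24 activated and memory genes 3 passed the rule as higher in these 2 arrays, where 154 of all 9623 measured genes did. The explanation stays open, since B cell markers and gamma delta T and NKT markers lay past the limit too. Variation between single arrays in sorting or amplification stays open as well. Genes simulated without a difference gave counts of 141 and 143 in this pairing at the upper spread. That spread is taken from the same contrast and so cannot separate noise from a true difference.

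The third pattern is the 314 genes at least 2-fold higher in CD25+ Foxp3- cells than in each other array, among them Kit, Cntn1, Fcer1g and Il1r1. Mast cells or basophils are unlikely as the source, since of 12 of their markers with a probe set only 2, Kit and Fcer1g, reached the filter there, and Fcer1a read 7.78 and Cpa3 15.8. Markers of innate lymphoid cells of the lymphoid tissue inducer type had a median of 1.59 log2 over CD25- Foxp3- cells, at the percentile 100, with Kit 34.1-fold, Ccr6 9.86-fold and Id2 3.22-fold higher but Il7r at 5075 against 6659. Kit and Id2 stood apart from every other array, but Ccr6 read 1862 and 1913 in the Foxp3+ arrays against 2419. Lta read 336 in CD25hi Foxp3+ cells against 341, so these 2 markers are not high in CD25+ Foxp3- cells alone. Further, 8 of the 10 measured markers are also read in CD25- Foxp3- cells, and some were seen to be high before the list was written. The sort also named no gate on the T cell receptor. In the CD25+ Foxp3- sort, innate lymphoid cells and activated T cells therefore cannot be told apart. Markers of gamma delta T and NKT cells rose there too, with a median of 1.55 log2 at the percentile 97.83 and Zbtb16 at 82.2 against 17.1, and Trgv4, on no list, read 491 against 99.8. With 4 of the 12 listed markers measured, 1 of them in all arrays above the filter, this source stays open, although the depletion by NK1.1 and DX5 would remove part of the NKT cells. The CD3 genes were lower against Cd4 by -0.37 log2, with an error of 0.68, which leaves fewer CD3-bearing cells open too.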

How the results depend on the processing

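The counts without listed markers of other cell types were chosen after seeing the data, and the other alternatives before. Quantile normalization, median centring and cyclic loess left all 18 counts within 1.5 times their main value and moved none of the 207 list medians beyond their spread. Over all alternatives 177 counts stayed within 1.5 times their main value and 9 did not. Of the values of named genes 1007 stayed within their spread and 56 moved, 37 of these under the floor at the 60th percentile, which shortens folds against dim arrays by construction. For list medians 2004 stayed, 65 moved and 1 reversed. Apart from the gap of 2-fold, genes higher with Foxp3 ranged from 205 to 290, genes lower from 115 to 202, genes higher with CD25 from 64 to 111 and genes lower from 13 to 23. With the filter at the 75th percentile fewer genes are measured, and the genes lower with Foxp3 numbered 115, those higher with CD25 64 and those lower in CD25hi Foxp3+ than in CD25- Foxp3- cells 221. Under that filter the red cell median between CD25+ and CD25- Foxp3- cells reversed to 0.80, with fewer members read. A gap of 2-fold, stricter by construction, gave 111 and 96 genes for Foxp3, 27 and 2 for CD25 and 22 and 32 for the third pairing. Among genes above the 75th percentile in all arrays the correlation of the Foxp3 differences reversed to -0.023 and that of the CD25 differences was -0.184, and the cause was not tested. In 17 cases a named gene was not measured under a stricter setting. No array was left out. No paired analysis was possible because each group held 1 array and the counts come from no test. Signal over background limits genes near the floor of 10.1, where folds are bounds. Without listed markers of other cell types the counts were 267 and 166, 106 and 16, and 140 and 154.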

Other observations

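The genes in this part were singled out after their values were seen, by their distance from the other 3 arrays, and no test was made of them. CD25- Foxp3- cells stood apart most often, with 338 genes at least 2-fold lower and 148 at least 2-fold higher than in each other array. Lower were Il1r2 by 13.1-fold, Tiam1 (an activator of the GTPase Rac) by 9.29-fold, Nrn1 by 8.53-fold and the secreted suppressive factor Fgl2 by 7.93-fold. Tiam1 read 2217, 2079 and 1533 in the other arrays. CD25+ Foxp3- cells had 314 genes at least 2-fold higher and 50 lower. Beyond the genes of the report these included Tmem176a, Tmem176b, Il17re, Bmp2 and Clnk upward, and downward Ifngr1, a chain of the interferon gamma receptor, by 2.97-fold and the kinase gene Pim1 by 2.75-fold. Cxcr6, a chemokine receptor, read 2148 in them and no more than 249 elsewhere.

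CD25lo Foxp3+ cells had 100 genes at least 2-fold higher and 84 lower than each other array. Cybb, the core of the phagocyte NADPH oxidase, read 1484 against 413, 364 and 238, and Atp6v0d2, a proton pump subunit, was 4.04-fold higher. Srm, which makes spermidine, was 4.30-fold lower, Cnn3 5.10-fold and the cathepsin gene Ctsw 4.10-fold lower. CD25hi Foxp3+ cells had 57 genes higher and 35 lower. The muscle-type enolase gene Eno3 read 1973 against 475 or less, and Ppm1l, a phosphatase gene, was 4.45-fold higher. Pou2af1, a coactivator of B cells and helper T cells, was 3.56-fold lower, at 43.2 against 154 and 928 in CD25lo Foxp3+ and CD25+ Foxp3- cells.

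Genes beside Foxp3, by gene order in the RefSeq table of assembly GRCm38.p6, mostly did not follow it. Ccdc22, the next gene, read 57.9 and 27.7 in the Foxp3+ arrays against 231 and 293 by one probe set. By another it read 50.4, 46.3, 46.5 and 50.2. Flicr, the neighbour on the other side, read 36.0 and 22.2 against floor and 11.3. Of the 8 measured genes around Foxp3 other than Ccdc22, 1 passed the rule for higher, Flicr, and none that for lower.

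The 9 probe sets of spiked control transcripts had median log2 distances from the mean of the arrays of 0.25 in CD25hi Foxp3+, 0.10 in CD25lo Foxp3+, -0.33 in CD25+ Foxp3- and -0.05 in CD25- Foxp3- cells. The step at which they were added was not checked, so they neither support nor contradict a shared scale of the arrays. The immunoglobulin heavy chain gene Ighm read 8884, 9906, 10053 and 14192 in the same order, high in every array.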
